A study of Mus musculus with 18 samples.

How the data were processed

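Total RNA of the fracture callus of female mice was extracted with Trizol and hybridised after biotin labelling to Affymetrix Mouse Genome 430 2.0 arrays, per the labels' protocols and the series' design text. The values used are the authors' deposited intensity table, 1 linear signal for each of 45101 probe sets on each of 18 arrays. The signal algorithm, software and scaling are not given in the sources used here. From the values, the mean of each array without its lowest and highest 2% of probe sets came to 150, the arrays' median signals ran from 35.99 to 72.38, and no logarithm had been taken. The labels give the age of each mouse group, the day after fracture and a replicate number of 1 to 3. They disagree on the strain, which one field gives as BALB/c and the design text as a C57BL/6 line.

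The following choices were made before the data were examined: the tests, the samples in each fit, the rule for scaling, the filter, the 35 gene lists, the rule for named genes and the alternatives, except those said here to be chosen after seeing the data. Signals were transformed as log2(value + 16), so that fold changes of dim genes are understated. The array medians of these values ran from 5.70 to 6.47, a difference of 0.77 that exceeded the 0.5 set beforehand, so the arrays were quantile normalized with normalizeBetweenArrays of limma 3.58.1 in R 4.3.3. The 64 Affymetrix control probe sets were left out of the tests, and a probe set was tested if it exceeded its array's median on at least 3 of the 18 arrays, which 27746 did. All 18 arrays entered 1 model with a mean per group (lmFit and eBayes with trend=TRUE), giving 17.3 total degrees of freedom. Adjusted p-values are Benjamini-Hochberg values per comparison, called under 0.05, and the interaction of age and day was tested with an F test on 2 contrasts.

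Gene symbols came from the platform annotation of 2016, in which 34958 probe sets have 1 gene, 932 several and 9211 none listed. Of the 34958 symbols, 34754 were updated through their gene identifier and 204 were kept, and probe sets with several genes were not named. A gene was represented by its tested probe set with the highest mean over the 18 arrays, giving 12921 genes. Of 5928 genes with more than 1 tested probe set, 187 had probe sets called in opposite directions in at least 1 comparison, and none of the genes named in the text did so in the comparison it is named for.

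The 35 gene lists covered blood, immune, muscle, fat, skin, nerve, vessel, cartilage, bone and connective tissue cells, signalling pathways, and stress and housekeeping functions, and 611 of their 740 genes were measured. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists within a comparison. fry tests whether the genes of a list move one way on balance and does not compare them with other genes. A list score is the mean log2 deviation of its genes from their averages over the 18 arrays. Genes were named by rule. Per comparison of ages these were up to 8 genes each way with the largest log2 difference among called genes whose 3 old and 3 young arrays did not overlap (for the mean over days, old on the same side in all 3 days). Per change over time they were up to 6 each way under the same rule, and per difference of changes up to 5 each way among called genes. Per list and comparison up to 4 members with the largest absolute difference were eligible, called or not, and so were the sex and strain checks and the 3' to 5' controls of Actb and Gapdh. The text names a part of these.

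The script was tested on simulated data made from the arrays' own means and spreads for old minus young on day 1, over 27746 probe sets with 200 changed. It called 1 of 50 probe sets changed by a log2 of 0.5, 14 of 50 changed by 1, 47 of 50 changed by 2 and 50 of 50 changed by 3, all in the right direction, and 4 of 27546 unchanged ones. With no change simulated it called 0. With 1 list shifted by -0.5, camera called 2 lists, the shifted list among them. Probe sets were simulated independently, without the structure that real arrays share, so these rates of false calls may not hold for the real arrays.

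The alternatives fixed beforehand were the values as deposited, centring of arrays on their medians, pseudocounts of 1 and 64, no filter or a filter at the 75th percentile, leaving out probe sets that can cross-hybridise, trend=FALSE, array weights, the replicate number as a block, an added 2-fold threshold, only the arrays of the groups compared, each array left out in turn, and for lists the estimated correlation, fry and the mean over a gene's probe sets. After seeing the data, further alternatives were added: the mean spike-in signal, the Actb 3' to 5' ratio or the skeletal muscle score as a covariate, the fit without young day 3 replicates 2 and 3, and the mean over days 3 and 5 only. The splits of the arrays into groups of the same sizes were refitted, all 10 for 3 against 3 arrays and 100 for the others. For the Erdr1 pattern, pairs of genes at most 3 tested genes apart on a chromosome were counted, leaving out Erdr1, Mid1 and Wdfy1, and compared with 10000 random sets of genes.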

Results

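Gene expression was measured in the femoral fracture callus, the repair tissue that forms around a broken bone, of female mice on days 1, 3 and 5 after fracture. Old mice were retired breeders of 8 months and young mice were 6 weeks of age. Breeding history and maturity go with age in every comparison of old with young mice and cannot be told apart from it. What is called age here covers them all. The 6 groups of age and day held 3 arrays each, 18 arrays in all, and no unfractured bone was analysed here. Nothing in the labels says that the 3 arrays of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value. Differences are given on a log2 scale with the standard error (SE) of the fit, where 1 is a doubling. Of the 27746 probe sets tested, calls rest on limma's moderated test at an adjusted p under 0.05. The first and second principal components held 43.4% and 15.3% of the variance. Arrays of a group correlated at 0.81 to 0.905 in young day 3 and at 0.893 to 0.976 in the other 5 groups.

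Young day 3 was the least uniform group. Its skeletal muscle score, the mean log2 deviation of muscle genes from their average over the 18 arrays, was 1.19 in replicate 1, -4.56 in replicate 2 and -0.22 in replicate 3. The corresponding group means were 1.07 ± 0.11 (SD, n = 3) in young day 1 and -0.15 ± 0.26 in old day 3. The Actb 3' to 5' signal ratio, which rises as RNA degrades, was 2.49 ± 0.202 in old day 1, 2.09 ± 0.0458 in young day 1, 1.51 ± 0.123 in old day 3 and 2.15 ± 0.516 in young day 3. On day 5 it was 1.59 ± 0.178 in old and 1.44 ± 0.145 in young mice. Eif2s3y, Uty and Kdm5d, genes of the Y chromosome, exceeded the array median on 0 of 18 arrays, and Xist, which is transcribed from the inactive X chromosome, gave signals of 1080 to 2350 on its brightest probe set.

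The change from day 1 to day 3 in young mice covers the days that follow the first inflammatory response to fracture. Among macrophage genes Trem2, a lipid-sensing receptor of myeloid cells, rose by 3.75 ± 0.28, Aif1 by 3.26 ± 0.42, Ms4a7 by 2.76 ± 0.32 and Gpnmb, a glycoprotein of lipid-laden macrophages, by 2.58 ± 0.36. Trem2 on day 1 lay below the array median, at 4.39 in young and 4.47 in old mice, so the size of its rise rests on the pseudocount. The carbonyl reductase gene Cbr2 rose by 2.96 ± 0.39. The Wnt modulator gene Sfrp2 rose by 3.12 ± 0.39, the small leucine-rich proteoglycan Ogn by 3.00 ± 0.33, Cthrc1 by 2.81 ± 0.32, Smpd3, a sphingomyelinase needed for bone mineralization, by 2.21 ± 0.35, and the stromal chemokine Cxcl12 by 1.72 ± 0.25. The score of the fibroblast and granulation tissue matrix list was -0.56 ± 0.34 (SD, n = 3) on day 1 and -0.54 ± 0.62 on day 3. Among inflammatory genes Cxcl3, a neutrophil attractant, changed by -4.45 ± 0.47 and the cytokines Il6 and Il11 by -3.69 ± 0.51 and -3.09 ± 0.61, while the monocyte attractant Ccl8 rose by 2.74 ± 0.54. Adjusted p for these genes ran from 3.73e-06 for Trem2 to 0.00403 for Ccl8 and Il11, and for each of them the 3 arrays of day 3 lay past all 3 of day 1. The naming rule required this of the genes with the largest differences.

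Of 24 measured macrophage and monocyte genes, 16 rose and 1 fell, or 18 and 2 adjusted over the list alone, with a median of 1.35 (camera, adjusted p = 5.78e-10). That list had an adjusted p = 0.761 with an estimated correlation. Of 22 genes of inflammatory cytokines and chemokines, 2 rose and 8 fell, or 2 and 10 adjusted over the list alone, with a median of -0.89 (camera, adjusted p = 0.000911), and an adjusted p = 0.869 with an estimated correlation. Immediate early genes, which respond within minutes to injury signals, fell in 10 of 19 cases and rose in 0. Adjusted over the list alone, 14 fell and 1 rose, with a median of -0.93 (camera, adjusted p = 3.26e-08, and adjusted p = 0.761 with an estimated correlation). Egr1 changed by -2.50 ± 0.42, Fosl1 by -2.35 ± 0.27 and the phosphatase gene Dusp1 by -2.20 ± 0.22. Of 19 erythroid genes 16 fell, or 18 adjusted over the list alone, with a median of -2.13 (camera, adjusted p = 4.38e-09, and adjusted p = 0.765 with an estimated correlation). Among them the blood group antigen gene Rhd changed by -2.46 ± 0.62 and Klf1, the master regulator of red cell genes, by -2.56 ± 0.68. The muscle genes Xirp1, Ankrd2 and Pdk4 changed by -4.89 ± 0.73, -4.31 ± 0.69 and -4.36 ± 0.63, in a comparison where the skeletal muscle score went from 1.07 ± 0.11 (SD, n = 3) to -1.19 ± 3.

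limma called 3690 probe sets, 2170 higher and 1520 lower on day 3 in young mice. With each array centred on its median the split was 2387 to 854. With array weights, which limma sets from each array's own spread, the count was 9944. Without 1 array the count ran from 1525 without young day 3 replicate 3 to 7044 without young day 3 replicate 1, and was 2446 without young day 3 replicate 2, 2006 without young day 1 replicate 1 and 2214 without young day 1 replicate 3. It was 521 without young day 3 replicates 2 and 3, an alternative chosen after seeing the data, in which the lone array is assumed to vary like the other groups. Klf1 lost its call without young day 3 replicate 3 (adjusted p = 0.124) and without young day 1 replicate 1, 2 or 3 (0.0636, 0.0554 and 0.0521), and over all its alternatives its adjusted p ran from 0.000342 to 0.237. Rhd lost its call without young day 3 replicate 3 (0.0967) or young day 1 replicate 1 (0.0549), with a range of 0.000482 to 0.236. The inflammatory list lost its camera call without young day 3 replicate 1 (adjusted p = 0.0953, over all alternatives of the 6 lists tested here 8.69e-13 to 0.869).

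The same interval in old mice asks whether their callus passed through the same change. Cthrc1, secreted by matrix-forming cells, rose in old mice by 4.43 ± 0.32, the collagen-like secreted factor C1qtnf3 by 4.33 ± 0.53, Sfrp2 by 4.32 ± 0.39, Ogn by 3.87 ± 0.33, Srpx2 by 3.71 ± 0.36 and Aspn, a proteoglycan that binds collagen, by 3.64 ± 0.32. The fibrillar collagen genes Col5a1 and Col5a2 rose by 2.68 ± 0.42 and 2.58 ± 0.29. Of macrophage genes, Trem2 rose by 4.27 ± 0.28, Ms4a7 by 3.18 ± 0.32, the complement gene C1qa by 3.07 ± 0.32 and the lipoprotein gene Apoe by 3.07 ± 0.27. The neutrophil attractants Cxcl3 and Cxcl2 changed by -3.80 ± 0.47 and -3.59 ± 0.65 and Il6 by -2.43 ± 0.51. Ankrd2 changed by -3.95 ± 0.69 and Psg28 by -3.96 ± 0.34. Erdr1 went from 12.02 ± 0.26 (SD, n = 3) to 7.04 ± 0.66 in log2 signal. For Erdr1 a strain difference between the old mice of these days cannot be told apart from a change over time. Adjusted p for the genes of this paragraph ran from 1.26e-07 for Trem2 to 0.00235 for Il6, and for each the 3 arrays of one day lay past all 3 of the other. The naming rule required this of the genes with the largest differences.

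Of 25 fibroblast and granulation tissue matrix genes, 20 rose, or 22 adjusted over the list alone, with a median of 1.69 (camera, adjusted p = 1.34e-10, and adjusted p = 0.505 with an estimated correlation). Of 24 macrophage and monocyte genes, 18 rose and 1 fell, in both adjustments including that adjusted over the list alone (median 1.36, camera, adjusted p = 1.79e-09, and adjusted p = 0.505 with an estimated correlation). Of 16 osteoblast and bone matrix genes, 10 rose, or 11 adjusted over the list alone (median 1.22, camera, adjusted p = 0.000351, and adjusted p = 0.647 with an estimated correlation). Ifitm5, a membrane protein of bone-forming cells, rose by 2.25 ± 0.42 and the bone proteoglycan Omd by 2.00 ± 0.46. Of 25 Wnt pathway genes, 13 rose and 2 fell, or 13 and 3 adjusted over the list alone (median 0.79, camera, adjusted p = 0.0234, and adjusted p = 0.647 with an estimated correlation). The members that rose included secreted Wnt inhibitors, Sfrp1 by 2.16 ± 0.29 and Dkk3 by 2.24 ± 0.37, and the matricellular gene Ccn4 by 2.31 ± 0.42. Of 16 skeletal progenitor genes, 8 rose and 1 fell, or 9 and 2 adjusted over the list alone (median 1.02, camera, adjusted p = 0.00721, and adjusted p = 0.505 with an estimated correlation). The limb mesenchyme factors Prrx2 and Prrx1 rose by 2.27 ± 0.33 and 1.71 ± 0.28.

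Of 9 MHC class II genes, which present antigen to helper T cells, 4 rose, or 5 adjusted over the list alone (median 0.79, camera, adjusted p = 0.0234, and adjusted p = 0.647 with an estimated correlation), with H2-Eb1 up by 1.28 ± 0.30 and Cd74 by 1.00 ± 0.25. Of 28 cell cycle genes, 7 rose, or 4 adjusted over the list alone (median 0.58, camera, adjusted p = 0.00887, and adjusted p = 0.784 with an estimated correlation), among them the mitotic kinesin Kif20a by 1.66 ± 0.35 and Cdk1 by 1.30 ± 0.34. Of 22 inflammatory genes, 2 rose and 8 fell, or 2 and 10 adjusted over the list alone (median -0.59, camera, adjusted p = 0.00341, and adjusted p = 0.647 with an estimated correlation), and Ccl8 was again among those that rose, by 3.11 ± 0.54. Of 19 immediate early genes 9 fell, or 10 adjusted over the list alone (camera, adjusted p = 1.22e-05, and adjusted p = 0.505 with an estimated correlation), with a median of -0.71. With arrays centred on their medians it was 0.06, still below the 0.47 of all probe sets (camera, adjusted p = 0.000507). Egr1 changed by -1.93 ± 0.42 and Dusp1 by -1.80 ± 0.22. Across the same interval the Actb 3' to 5' ratio of old mice went from 2.49 ± 0.202 (SD, n = 3) to 1.51 ± 0.123, and the bacteriophage cre spike-in signal from 44900 ± 8600 to 18800 ± 5160. The skeletal muscle score of old mice went from 1.08 ± 0.30 to -0.15 ± 0.26 and the erythroid score from 1.03 ± 0.81 to -0.48 ± 0.33.

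limma called 8266 probe sets in old mice, 4915 higher and 3351 lower on day 3. The split was 3961 to 5535 with the values as deposited and 10976 to 1807 with arrays centred on their medians. With that centring the median of all probe sets was 0.47, against 0.058 after quantile normalization. Without old day 3 replicate 2 the count was 5177, and without each other array it moved by less than 1.5 times. The Wnt list lost its camera call without old day 1 replicate 1 or 2 (adjusted p = 0.0642 and 0.0613), the MHC class II list without old day 1 replicate 1 or 3 or old day 3 replicate 3 (0.129, 0.0645 and 0.0599) and the cell cycle list without old day 1 replicate 1 (0.36). Across alternatives the adjusted p of the 10 lists tested here ran from 1.33e-14 to 0.995. The calls overlapped between the ages: 1485 probe sets were higher on day 3 in both, where 384.4 were expected of independent calls, 780 were lower in both against 183.6 expected, and 3 and 11 were called in opposite directions.

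**Figure D1:**
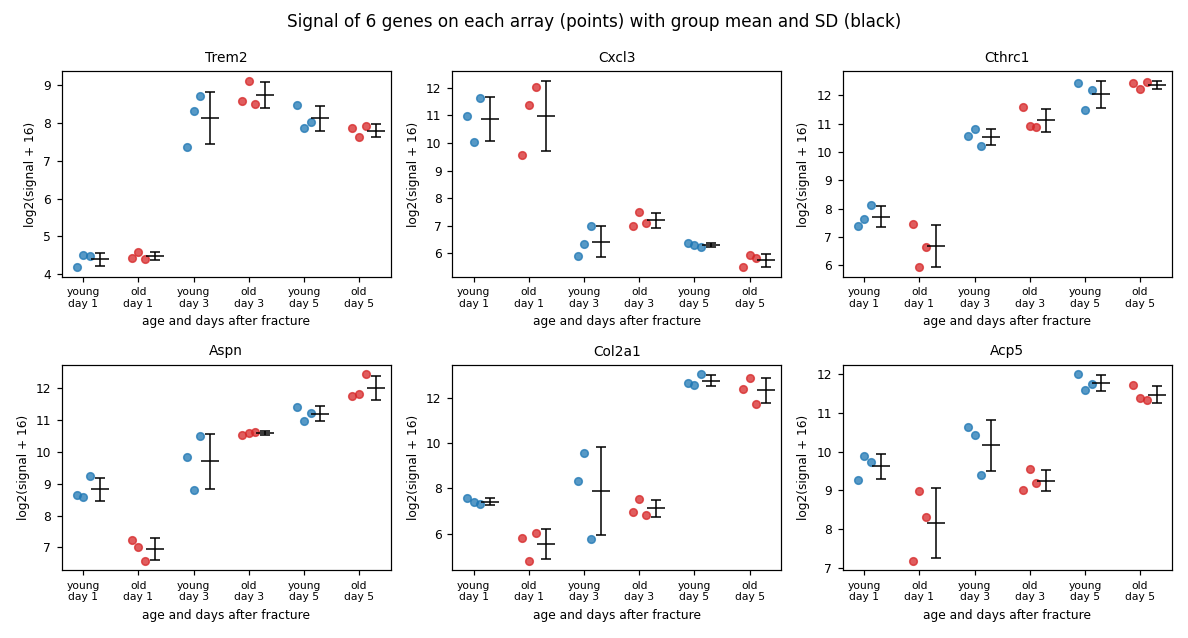
Log2(signal + 16) after quantile normalization (y axis) of 6 genes on each array (points) by age and day (x axis), with the group mean and SD of n = 3 in black. Trem2 and Cthrc1 rose and Cxcl3 fell from day 1 to day 3 in both ages, Col2a1 and Acp5 rose from day 3 to day 5, and Aspn on day 1 was 6.95 ± 0.34 in old and 8.83 ± 0.36 in young mice.

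Between day 3 and day 5 the question in young mice was which genes of cartilage and bone formation followed. Col2a1, the main collagen of cartilage, rose by 4.85 ± 0.62, Col9a3 by 4.56 ± 0.40, Col9a1 by 3.75 ± 0.43 and Cnmd, which keeps cartilage free of vessels, by 3.32 ± 0.60. C1qtnf3 rose by 4.08 ± 0.53 and the matrix genes Col12a1, Col5a1 and Col6a2 by 2.65 ± 0.39, 2.55 ± 0.42 and 2.55 ± 0.38. Ocstamp, a protein of osteoclast fusion, rose by 2.37 ± 0.31, the gelatinase Mmp9 by 1.95 ± 0.37 and Acp5, the tartrate-resistant acid phosphatase of osteoclasts, by 1.61 ± 0.36. The bone matrix genes Alpl, a mineralization enzyme, and Col1a1 rose by 1.73 ± 0.44 and 1.41 ± 0.35. The fetal muscle myosin gene Myh8 rose by 3.52 ± 0.65. The membrane collagenase gene Mmp14, the growth factor gene Tgfb2 and the Wnt antagonists Dkk3 and Frzb rose by 2.04 ± 0.33, 1.43 ± 0.27, 2.14 ± 0.37 and 2.11 ± 0.36. The myeloid chemokine gene Ccl6, the scavenger receptor gene Cd163 and the acute phase gene Saa3 changed by -1.51 ± 0.37, -1.70 ± 0.35 and -2.21 ± 0.38. Adjusted p ran from 4.21e-05 for Col9a3 to 0.0279 for Alpl, and for each gene the 3 arrays of day 5 lay past all 3 of day 3. The naming rule required this of the genes with the largest differences.

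Of 23 chondrocyte genes 15 rose, or 18 adjusted over the list alone (median 2.05, camera, adjusted p = 1.55e-14, and adjusted p = 0.0726 with an estimated correlation). Of 25 fibroblast matrix genes 19 rose, or 22 adjusted over the list alone (median 1.37, camera, adjusted p = 1.85e-17, and adjusted p = 0.194 with an estimated correlation). Of 13 osteoclast genes 8 rose, or 9 adjusted over the list alone (median 1.08, camera, adjusted p = 3.9e-06, and adjusted p = 0.13 with an estimated correlation). Of 16 osteoblast genes 6 rose, or 11 adjusted over the list alone (median 1.03, camera, adjusted p = 8.39e-06, and adjusted p = 0.36 with an estimated correlation). Of 22 matrix proteases and inhibitors 7 rose and 1 fell, or 11 and 1 adjusted over the list alone (median 0.91, camera, adjusted p = 8.39e-06, and adjusted p = 0.289 with an estimated correlation). Of 22 endothelial genes 5 rose, or 11 adjusted over the list alone (median 0.74, camera, adjusted p = 0.000359, and adjusted p = 0.36 with an estimated correlation). The Actb ratio of young mice went from 2.15 ± 0.516 (SD, n = 3) to 1.44 ± 0.145 over the same days.

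limma called 1773 probe sets, 1128 higher and 645 lower on day 5 in young mice. The split was 1560 to 1445 with the values as deposited and 4167 to 594 with arrays centred on their medians. With that centring the median of all probe sets was 0.23, against -0.003 after quantile normalization. The count was 12636 with array weights, 16 with the Actb ratio as a covariate, 30 with the spike-in signal as a covariate, 15 from the 6 arrays alone and 129 without young day 3 replicates 2 and 3, the covariates and the last of these chosen after seeing the data. Without 1 array it was 5523 (young day 3 replicate 1), 1038 (young day 3 replicate 2), 372 (young day 3 replicate 3), 287 (young day 5 replicate 1) and 520 (young day 5 replicate 3). Without young day 3 replicate 3, young day 5 replicate 1 or young day 5 replicate 3, Acp5, Alpl, Col1a1, Ccl6 and Cd163 lost their calls, at adjusted p of 0.063 to 0.152, 0.052 to 0.145 and 0.0546 to 0.0976. Alpl and Col1a1 did so without young day 3 replicate 2 (0.0584 and 0.0763), and Col1a1 and Ccl6 without young day 5 replicate 2 (0.0634 and 0.0546). For the 21 genes named, the adjusted p over all alternatives ran from 3.37e-08 to 0.784.

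Between day 3 and day 5 in old mice, Col2a1 rose by 5.20 ± 0.62, Col9a1 by 4.57 ± 0.43, Col9a3 by 4.15 ± 0.40 and Cnmd by 4.07 ± 0.60. Myh8 rose by 4.62 ± 0.65, Ctsk, the collagen-degrading protease of osteoclasts, by 2.29 ± 0.32 and Acp5 by 2.21 ± 0.36. Fbn2, a microfibril protein of developing tissue, and Frzb rose by 1.92 ± 0.40 and 1.97 ± 0.36. Among myeloid and platelet genes Arg1, an arginase of repair macrophages, changed by -2.70 ± 0.48, Saa3 by -2.08 ± 0.38, Ccl6 by -2.06 ± 0.37, the monocyte chemokine receptor gene Ccr2 by -1.82 ± 0.32, and the platelet chemokine genes Ppbp and Pf4 by -1.96 ± 0.43 and -1.93 ± 0.25. Adjusted p ran from 4.07e-05 for Col9a1 to 0.0493 for Ppbp, and for each gene the 3 arrays of day 5 lay past all 3 of day 3. The naming rule required this of the genes with the largest differences.

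Of 23 chondrocyte genes 13 rose in old mice, or 18 adjusted over the list alone (median 2.08, camera, adjusted p = 8.05e-35), and of 13 osteoclast genes 5 rose, or 8 adjusted over the list alone (median 1.26, camera, adjusted p = 1.62e-10). These were the 2 lists of the 35 whose call held with an estimated correlation in any comparison (adjusted p = 0.00178 and adjusted p = 0.021 with an estimated correlation). Of 25 fibroblast matrix genes 2 rose, or 20 adjusted over the list alone (median 0.99, camera, adjusted p = 1.38e-19, and adjusted p = 0.0956 with an estimated correlation). Of 14 muscle regeneration genes 2 rose, or 8 adjusted over the list alone (median 1.78, camera, adjusted p = 4.45e-10, and adjusted p = 0.158 with an estimated correlation). Of 24 macrophage genes 4 fell, or 18 adjusted over the list alone (median -0.90, camera, adjusted p = 1.01e-18, and adjusted p = 0.0956 with an estimated correlation). Of 12 platelet and megakaryocyte genes 2 fell, or 11 adjusted over the list alone (median -1.55, camera, adjusted p = 5.1e-15, and adjusted p = 0.0956 with an estimated correlation).

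limma called 164 probe sets in old mice, 136 higher and 28 lower on day 5, and 2000 with array weights. Without 1 array the count was 63 (old day 3 replicate 2), 49 (old day 3 replicate 3), 67 (old day 5 replicate 1), 82 (old day 5 replicate 2) and 65 (old day 5 replicate 3). Of the 15 genes named, Col2a1, Col9a1, Col9a3, Cnmd, Ctsk, Acp5, Myh8 and Pf4 held without each array, and the other 7 lost their calls without at least 1. Ppbp lost its call without each of the 6 arrays. The adjusted p of the lost calls ran to 0.114 without old day 3 replicate 1 (Fbn2 and Ppbp), to 0.128 without replicate 2 (Fbn2, Frzb, Arg1, Ccr2, Ppbp and Ccl6) and to 0.314 without replicate 3 (Fbn2, Frzb, Ccr2, Ppbp, Ccl6 and Saa3). It ran to 0.167 without old day 5 replicate 1 (Fbn2, Frzb, Arg1, Ppbp and Saa3), to 0.172 without replicate 2 (Frzb, Ccr2, Ppbp and Saa3) and to 0.257 without replicate 3 (Fbn2, Frzb, Arg1, Ppbp and Ccl6). Over all alternatives the adjusted p of the 15 genes ran from 4.24e-08 to 0.314. Young and old mice shared 114 probe sets that were higher on day 5, where 5.5 were expected of independent calls (Fisher's exact test, 5.31e-137), and 8 that were lower, where 0.7 were expected (1.68e-07). The test takes probe sets as independent, which those of the same gene are not. Its p-values therefore overstate the evidence and do not measure the spread between animals.

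On day 1 the question was whether the callus differed by age at the start of healing. In old mice C1qtnf1 differed by -2.05 ± 0.27, Srpx2 by -2.03 ± 0.36, the collagen gene Col11a1 by -1.99 ± 0.35 and Aspn by -1.88 ± 0.32. Fap differed by -1.50 ± 0.26, Bmp1 by -1.52 ± 0.26 and Ctsk by -1.64 ± 0.32. Abca3, Cep41, Ngef and Snx7 were also lower, by -2.06 ± 0.39, -1.76 ± 0.30, -1.76 ± 0.27 and -1.70 ± 0.25. Higher in old mice were Epb41l5 by 1.62 ± 0.27, Chrm1 by 1.30 ± 0.25 and Zfp239 by 1.10 ± 0.21. The old day 1 means of C1qtnf1, Srpx2, Abca3, Cep41, Ngef and Snx7 lay below the array median, as did the young mean of Epb41l5. Their sizes rest on the pseudocount. Of these called genes with more than 1 tested probe set, only Col11a1 was called on all. Adjusted p ran from 0.0108 for C1qtnf1 to 0.0453 for Ctsk, and for each gene all 3 old arrays lay on one side of all 3 young arrays. The naming rule required this of all but Fap, Bmp1 and Ctsk. By the brightest tested probe set of each gene, 3 genes were called higher and 28 lower in old mice. Chance alone separates 3 against 3 arrays for 10% of genes, called or not. A further 21 genes were called only by another of their probe sets.

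Of 16 osteoblast and bone matrix genes 1 was lower in old mice on day 1, or 12 adjusted over the list alone, with a median of -1.05 (camera, adjusted p = 2.84e-10, and adjusted p = 0.354 with an estimated correlation). Omd differed by -2.22 ± 0.46 (adjusted p = 0.053), Col1a1 by -1.46 ± 0.35 (0.0963), and the osteocyte genes Dmp1 and Phex by -1.72 ± 0.53 (0.176) and -1.49 ± 0.38 (0.111). None of these 4 passed the test, with all 3 old arrays below all 3 young arrays for each. Of 25 fibroblast matrix genes 3 were lower, or 14 adjusted over the list alone (median -0.72, camera, adjusted p = 1.1e-12, and adjusted p = 0.354 with an estimated correlation). The 28 cell cycle genes had a median of -0.41 (camera, adjusted p = 0.00017, and adjusted p = 0.914 with an estimated correlation) and the 24 interferon response genes one of 0.37 (camera, adjusted p = 0.000917, and adjusted p = 0.914 with an estimated correlation), with 0 members called in either, also when adjusted over the list alone. On these arrays the Actb ratio was 2.49 ± 0.202 (SD, n = 3) in old and 2.09 ± 0.0458 in young mice, and the cre spike-in signal 44900 ± 8600 and 33400 ± 6820. The epidermis score, from 4 measured genes, was 0.59 ± 0.06 in old and -0.03 ± 0.29 in young mice.

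limma called 64 probe sets on day 1, 8 higher and 56 lower in old mice. With the values as deposited it called 6, of which 0 were higher. With arrays centred on their medians the median of all probe sets was -0.19, against -0.025 after quantile normalization. From the 6 day 1 arrays alone, and with the spike-in signal as a covariate, the count was 0, and with the Actb ratio as a covariate it was 4. With array weights it was 18. At an unadjusted p under 0.05 limma passed 3373 probe sets. The count was 10 without young day 1 replicate 3 and 307 without old day 1 replicate 2. Without young day 1 replicate 3 each of the 14 called genes named here lost its call except C1qtnf1, at adjusted p of 0.0507 to 0.153. Calls were also lost without old day 1 replicate 1 (Epb41l5, Chrm1, Zfp239, Fap, Ctsk and Cep41, 0.0505 to 0.0906), old day 1 replicate 3 (Chrm1, Srpx2, Col11a1, Aspn, Ctsk and Cep41, 0.0542 to 0.06), young day 1 replicate 1 (Chrm1, Zfp239, Ctsk and Abca3, 0.053 to 0.0963) and young day 1 replicate 2 (Zfp239, Srpx2, Ctsk and Abca3, 0.0643 to 0.102). Omd gained a call without old day 1 replicate 2 (0.0195), and the cell cycle list lost its own without old day 1 replicate 1 (0.828). Over all alternatives the adjusted p of the 14 genes ran from 0.000679 to 0.577.

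**Figure D2:**
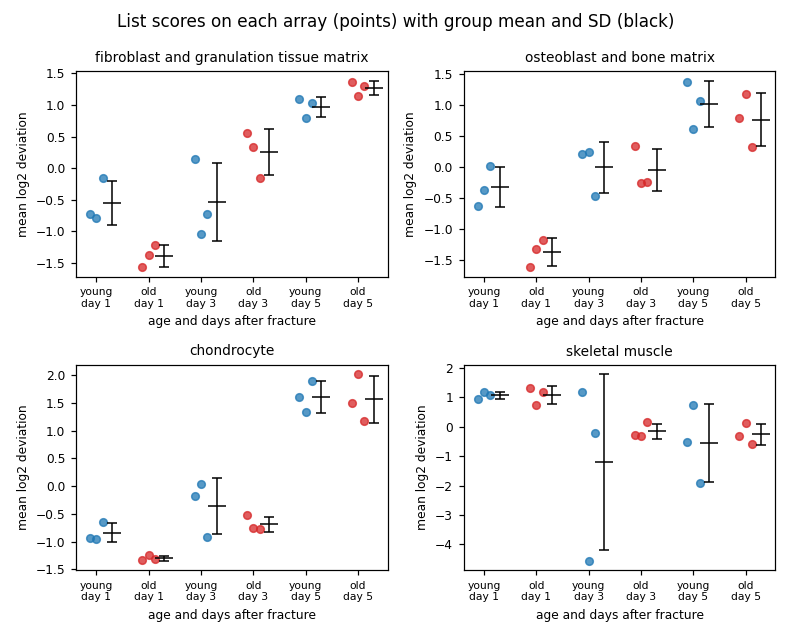
Mean log2 deviation of the genes of 4 lists from their average over all arrays (y axis) for each array (points) by age and day (x axis), with the group mean and SD of n = 3 in black. The fibroblast matrix score was -1.39 ± 0.18 in old and -0.56 ± 0.34 in young mice on day 1 and 0.25 ± 0.36 and -0.54 ± 0.62 on day 3, and the skeletal muscle score of young day 3 spread from -4.56 to 1.19.

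Old and young mice were compared in the same way on day 3. Erdr1, named for its role in erythroid differentiation, differed by -4.48 ± 0.36 (adjusted p = 5.15e-06), Mid1, a microtubule-associated ubiquitin ligase gene of the X chromosome, by -2.67 ± 0.30 (0.000727) and the uncharacterised gene G530011O06Rik by -2.13 ± 0.35 (0.0283). Higher in old mice were Slc27a3, a fatty acid transporter family gene, by 1.83 ± 0.24 (0.00423), the retinoic acid binding protein gene Crabp2 by 1.69 ± 0.21 (0.00276) and the centrosomal gene Cep152 by 1.10 ± 0.19 (0.049). For these 3 genes the young day 3 mean lay below the array median, for Slc27a3 at a log2 signal of 4.35, so their sizes rest on the pseudocount. The Erdr1 values are of a probe set that can cross-hybridise. The gene's other tested probe set, whose mean lay below the array median in all groups but old day 1, gave -0.81 ± 0.47 (0.555) on day 3 and -1.17 ± 0.47 (1) on day 5. For each of the 6 genes all 3 old arrays lay on one side of all 3 young arrays, as the naming rule required, so it adds no support. By the brightest tested probe set of each gene these were all, 3 higher and 3 lower, that were called without overlap. Chance alone separates 3 against 3 arrays for 10% of genes, called or not. A further 2 genes were called only by other probe sets. One was Wdfy1, an endosomal adaptor gene, which was higher in old mice by 1.58 ± 0.22 (0.00712) and 1.42 ± 0.24 (0.0342) on 2 other probe sets, each without overlap. Its brightest gave 1.10 ± 0.21 (0.0775, over the alternatives 2.03e-05 to 0.728).

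The fibroblast matrix list had a median of 0.93 on day 3 (camera, adjusted p = 6.6e-11, and adjusted p = 0.625 with an estimated correlation), with 0 of 25 members called and 16 higher adjusted over the list alone. Postn, a matrix protein of healing tissue, differed by 1.24 ± 0.40 (adjusted p = 0.273) and Col5a1 by 1.40 ± 0.42 (0.234), with 2 of 3 old arrays above all young arrays. With the Actb ratio as a covariate, chosen after seeing the data, the fibroblast list lost its call (median 0.23, camera, adjusted p = 0.132, over all alternatives of the 3 lists tested here 1.03e-12 to 0.625). The 9 MHC class II genes had a median of 0.77 (camera, adjusted p = 9.42e-06, and adjusted p = 0.625 with an estimated correlation), with 0 called and 5 higher adjusted over the list alone. Cd74 differed by 1.32 ± 0.25 (0.0775) and H2-Ab1 by 1.19 ± 0.30 (0.162). The 22 matrix proteases and inhibitors had a median of 0.45 (camera, adjusted p = 0.000168, and adjusted p = 0.625 with an estimated correlation), with 0 called and 4 higher adjusted over the list alone, and Timp1, an inhibitor of matrix proteases, differed by 1.26 ± 0.30 (0.146). For Cd74, H2-Ab1 and Timp1 all 3 old arrays lay above all 3 young arrays. The Actb ratio was 1.51 ± 0.123 (SD, n = 3) in old day 3 and 1.56, 2.52 and 2.37 in young day 3 replicates 1, 2 and 3.

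limma called 16 probe sets on day 3, 7 higher and 9 lower in old mice. With array weights it called 8033, 4403 higher and 3630 lower. The split was 124 to 19 with arrays centred on their medians. With that centring the median of all probe sets was 0.22, against 0.012 after quantile normalization. The count was 2 with the Actb ratio as a covariate and 3 without young day 3 replicates 2 and 3, both chosen after seeing the data. Without 1 array it was 1605 (young day 3 replicate 1), 10 (young day 3 replicate 2), 5 (young day 3 replicate 3), 8 (old day 3 replicate 1) and 7 (old day 3 replicate 2). Cep152 lost its call without old day 3 replicate 1, 2 or 3 (0.144, 0.267 and 0.0935) or young day 3 replicate 2 or 3 (0.186 and 0.148), and G530011O06Rik without the same arrays (0.144, 0.0628, 0.0829, 0.0605 and 0.221). Without young day 3 replicate 1 Cd74, Postn, Col5a1 and Timp1 gained calls (0.0226, 0.0155, 0.00962 and 0.013). Over all alternatives the adjusted p of the 6 called genes ran from 1.46e-07 to 0.728.

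On day 5 Erdr1 and Mid1 were again lower in old mice, by -5.18 ± 0.36 (adjusted p = 1.01e-06) and -2.69 ± 0.30 (0.000653), with all 3 old arrays below all 3 young arrays, as the naming rule required. By the brightest tested probe set of each gene these were all that were called, 0 higher and 2 lower. Chance alone separates 3 against 3 arrays for 10% of genes, called or not. Marrow lists were lower in old mice by camera. The 19 erythroid genes had a median of -1.55 (camera, adjusted p = 5.36e-18, and adjusted p = 0.458 with an estimated correlation), with 0 called and 11 lower adjusted over the list alone. Alas2, the first enzyme of red cell heme synthesis, differed by -2.14 ± 0.53 (adjusted p = 0.932), and the band 3 anion exchanger gene Slc4a1 by -2.34 ± 0.83 (1). The 16 neutrophil granule genes had a median of -1.07 (camera, adjusted p = 3.95e-12, and adjusted p = 0.458 with an estimated correlation), the 12 platelet genes one of -0.92 (camera, adjusted p = 1.05e-11, and adjusted p = 0.458 with an estimated correlation) and the 17 B cell genes one of -0.82 (camera, adjusted p = 1.92e-07, and adjusted p = 0.458 with an estimated correlation). Adjusted over the list alone, 0, 7 and 0 of their members were lower. Mpo, the myeloperoxidase gene, differed by -1.46 ± 0.52 (1), Ppbp by -1.48 ± 0.43 (1) and the recombinase gene Rag1 by -1.39 ± 0.44 (1).

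The 14 muscle regeneration genes had a median of 0.83 on day 5 (camera, adjusted p = 4.19e-06, and adjusted p = 0.5 with an estimated correlation), with 0 called, also when adjusted over the list alone, and the acetylcholine receptor gene Chrna1 differed by 1.41 ± 0.65 (adjusted p = 1). Sfrp1 differed by 1.75 ± 0.29 (0.0675). All 3 old arrays lay past all 3 young arrays for Alas2, Mpo, Ppbp, Rag1 and Sfrp1, and 2 of 3 did for Slc4a1 and Chrna1. The erythroid score was -1.46 ± 0.99 (SD, n = 3) in old and -0.01 ± 0.87 in young mice, and the skeletal muscle score -0.26 ± 0.35 and -0.55 ± 1.33. limma called 3 probe sets on day 5, 0 higher and 3 lower, with 941 at an unadjusted p under 0.05, and the count was 3 without each array in turn and 78 with array weights, 46 higher and 32 lower. With the values as deposited it called 7, 3 higher and 4 lower, and with arrays centred on their medians 6, 2 higher and 4 lower. The adjusted p of Erdr1 and Mid1 ran over all alternatives from 2.62e-09 to 0.0103.

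**Figure D3:**
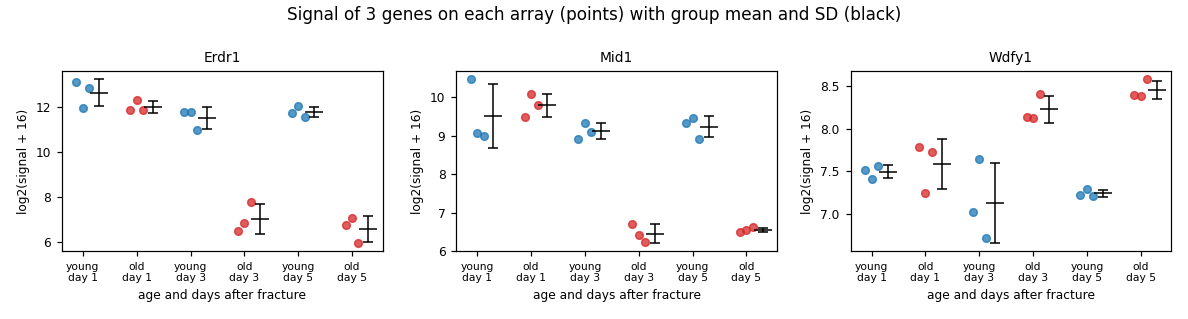
Log2(signal + 16) after quantile normalization (y axis) of Erdr1, Mid1 and Wdfy1 on each array (points) by age and day (x axis), with the group mean and SD of n = 3 in black. On the 6 arrays of old day 3 and day 5 Erdr1 lay at 5.98 to 7.78 and on the other 12 at 10.98 to 13.11, and the ranges of Mid1 and Wdfy1 were likewise separate.

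Averaged over the 3 days, Wdfy1 was higher in old mice by 0.80 ± 0.12 (adjusted p = 0.0188). Erdr1 was lower by -3.43 ± 0.21 (1.12e-07), the lipoxygenase gene Alox15 by -1.40 ± 0.21 (0.0188) and G530011O06Rik by -1.28 ± 0.20 (0.0254). For each the old group mean lay on the same side of the young group mean on all 3 days, which the naming rule required. limma called none of the 4 on day 1 (adjusted p of 0.138 to 0.953). The log2 signals of old and young mice on day 1 were 7.59 and 7.49 for Wdfy1, 12.02 and 12.64 for Erdr1, 6.67 and 6.77 for G530011O06Rik and 5.27 and 6.62 for Alox15. The 16 osteoblast genes had a median of -0.33 (camera, adjusted p = 2.29e-07, and adjusted p = 0.493 with an estimated correlation), the 8 osteocyte genes one of -0.43 (camera, adjusted p = 0.00198, and adjusted p = 0.382 with an estimated correlation) and the 17 B cell genes one of -0.45 (camera, adjusted p = 2.63e-07, and adjusted p = 0.493 with an estimated correlation). Over all probe sets 0 of their members were called, and 4, 4 and 1 were lower and 0, 1 and 0 higher adjusted over the list alone. limma called 8 probe sets, 3 higher and 5 lower, with 1655 at an unadjusted p under 0.05, and with the values as deposited 12, 6 higher and 6 lower. With array weights it called 101, 58 higher and 43 lower.

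Without young day 3 replicate 1 the mean over days gave 22 calls. It gave 3 without old day 3 replicate 2 or 3, old day 5 replicate 2 or any 1 of the 3 young day 5 arrays, 4 without old day 3 replicate 1 or old day 5 replicate 1, and 5 without old day 5 replicate 3 or young day 1 replicate 1. Erdr1 held without each array. Wdfy1 lost its call without any 1 of the 6 old arrays of day 3 and day 5, the 3 young day 5 arrays or young day 1 replicate 1 (0.0506 to 0.0728). Alox15 lost its call without old day 3 replicate 1, 2 or 3, old day 5 replicate 2, young day 1 replicate 1 or 3 or any 1 of the young day 5 arrays (0.0506 to 0.0808). G530011O06Rik did so without the same arrays, old day 5 replicate 1 or young day 3 replicate 3 (0.0562 to 0.0956). For the 4 genes the adjusted p over all alternatives ran from 1.1e-08 to 0.125.

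Whether the change over time differed by age was tested as an interaction. From day 1 to day 3 the change of the thrombospondin gene Thbs3 was more positive in old than in young mice by 3.85 ± 0.76 (adjusted p = 0.0349), that of Srpx2 by 2.80 ± 0.50 (0.0272), Aspn by 2.76 ± 0.46 (0.0199), Col12a1 by 2.68 ± 0.56 (0.0419), Col5a1 by 2.65 ± 0.59 (0.0495), Timp1 by 2.05 ± 0.43 (0.0419) and Bmp1 by 1.87 ± 0.37 (0.0349). The centrosomal gene Cdk5rap2 differed by 3.08 ± 0.46 (0.011) and Nol4l by 2.98 ± 0.61 (0.0419). Erdr1 differed by -3.86 ± 0.50 (0.00778), Mid1 by -2.95 ± 0.43 (0.011), Psg28 by -2.77 ± 0.48 (0.0249), the adhesion receptor gene Adgrv1 by -2.60 ± 0.50 (0.0328) and Dach1, a transcriptional repressor of development, by -2.33 ± 0.51 (0.0487). Of 25 fibroblast matrix genes the difference was positive and called in 6, or 20 adjusted over the list alone, with a median of 1.51 (camera, adjusted p = 6.29e-18, and adjusted p = 0.544 with an estimated correlation). The fibroblast matrix score differed by 1.63 (95% interval 0.77 to 2.48), and by 0.75 (-0.16 to 1.66) with the Actb ratio as a covariate, chosen after seeing the data. The 16 osteoblast genes had a median of 1.03, with 0 called and 6 positive adjusted over the list alone (camera, adjusted p = 0.000251, and adjusted p = 0.62 with an estimated correlation). The Actb ratio went from 2.49 ± 0.202 (SD, n = 3) to 1.51 ± 0.123 in old mice and from 2.09 ± 0.0458 to 2.15 ± 0.516 in young mice over these days.

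limma called 164 probe sets for this difference, 100 positive and 64 negative, and 2535 with array weights. The split was 112 to 168 with the values as deposited and 1923 to 144 with arrays centred on their medians. With that centring the median of all probe sets was 0.42, against 0.047 after quantile normalization. With the Actb ratio as a covariate limma called 0, against 4360 at an unadjusted p under 0.05 without it, and with the spike-in signal 1. Without young day 3 replicates 2 and 3 it called 8, and these 3 alternatives were chosen after seeing the data. Without 1 array the count was 461 (old day 1 replicate 2), 55 (young day 1 replicate 2), 41 (young day 1 replicate 3), 6 (old day 3 replicate 1), 15 (old day 3 replicate 2), 1737 (young day 3 replicate 1), 58 (young day 3 replicate 2) and 17 (young day 3 replicate 3). Of the 14 genes named, Erdr1 and Mid1 held without each array. Cdk5rap2 lost its call without old day 3 replicate 1 (0.0547), and Aspn without old day 3 replicate 1 or 2 (0.0594 and 0.0709). Srpx2 and Psg28 lost theirs without old day 3 replicate 1 or 2, young day 1 replicate 2 or 3 or young day 3 replicate 3 (0.052 to 0.0948). The other 8 lost theirs without arrays among the 12 of days 1 and 3 other than young day 3 replicate 1, at adjusted p of 0.0506 to 0.144. Over all alternatives the adjusted p of the 14 genes ran from 0.000104 to 0.525.

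From day 3 to day 5 limma called 0 probe sets for the difference between the ages, with 1791 at an unadjusted p under 0.05. Ppbp differed by -2.28 ± 0.61 (adjusted p = 0.733) and Cd74 by -1.63 ± 0.36 (0.602). With array weights limma called 4806, 1999 positive and 2807 negative. Without young day 3 replicate 1 it called 8. With arrays centred on their medians the median of all probe sets was -0.22, against -0.008 after quantile normalization. Of the 12 platelet genes 9 were negative adjusted over the list alone, with a median of -1.48 (camera, adjusted p = 3.82e-10, and adjusted p = 0.654 with an estimated correlation). The 9 MHC class II genes had a median of -0.94, with 3 negative adjusted over the list alone (camera, adjusted p = 3.37e-06, and adjusted p = 0.654 with an estimated correlation). The F test of both changes together called 18 probe sets, with the largest of its differences positive in 14 and negative in 4, and 3244 at an unadjusted p under 0.05. With the values as deposited it called 3, of which 0 were positive, and with arrays centred on their medians 264, of which 236 were positive. With array weights it called 4297, of which 2337 were positive. Without 1 array the F test called 731 (young day 3 replicate 1), 53 (old day 1 replicate 2), 6 (young day 3 replicate 3), 5 (old day 1 replicate 1 or young day 5 replicate 1 or 2), 3 (old day 3 replicate 1 or 2, any 1 of the old day 5 arrays or young day 5 replicate 3) and 2 (young day 1 replicate 2 or 3).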

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

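Of the tests in this part, those of array scaling and of a strain difference for Erdr1, Mid1 and Wdfy1, that of RNA quality for the fibroblast list on day 3 and the comparison of epidermis and plasma cells with B cells on day 1 were chosen only after the result was seen. So were the covariates used in 5 of the other tests, the spike-in mean, the Actb ratio and the skeletal muscle score, as settings of the fit.

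Each result in this paragraph and the next stood out because limma, or for lists camera at its preset correlation, called a difference between old and young mice in the change over time. For the change from day 1 to day 3 limma called 164 probe sets and camera 10 lists, and the F test over both intervals called 18 probe sets. The largest positive differences were Thbs3 at 3.85, Cdk5rap2 at 3.08, Nol4l at 2.98, Srpx2 at 2.80 and Aspn at 2.76. The largest negative ones were Erdr1 at -3.86, Mid1 at -2.95, Psg28 at -2.77, Adgrv1 at -2.60 and Dach1 at -2.33. The list medians were 1.51 for fibroblast matrix, 1.03 for osteoblast and bone matrix, 0.84 for the Wnt pathway, 0.74 for platelets, 0.66 for MHC class II, 0.65 for the cell cycle, 0.49 for matrix proteases, 0.39 for the unfolded protein response, 0.36 for the BMP and TGF-beta pathway and -0.52 for the interferon response. With an estimated correlation their adjusted p ran from 0.544 to 0.941, so none held, and 72 of 100 splits of the arrays gave as many lists. Of these lists fibroblast matrix, osteoblast and matrix protease kept their calls without each array. With the Actb ratio as a covariate the difference of the fibroblast matrix score went from 1.63 (interval 0.77 to 2.48) to 0.75 (-0.16 to 1.66), which reaches 0, although camera still called the list (median 0.76, adjusted p = 0.000162). Calls were lost without old day 1 replicate 1 (cell cycle, MHC class II, Wnt and platelets, adjusted p of 0.0662 to 0.376), old day 1 replicate 2 (BMP and Wnt, 0.058 to 0.151), old day 1 replicate 3 (MHC class II, 0.129), old day 3 replicate 1 (interferon and BMP, 0.0737) and old day 3 replicate 3 (MHC class II, BMP and platelets, 0.0622 to 0.322). They were also lost without young day 1 replicate 1 (MHC class II, 0.22), replicate 2 (platelets, 0.0525) or replicate 3 (BMP, Wnt, platelets and unfolded protein response, 0.0505 to 0.101), and without young day 3 replicate 1 (MHC class II, BMP and platelets, 0.0939 to 0.296), replicate 2 (Wnt, 0.11) or replicate 3 (BMP and platelets, 0.0723 to 0.151). Over all alternatives the adjusted p of the 10 lists ran from 4.25e-21 to 0.941.

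For the change from day 3 to day 5 limma called 0 probe sets (1791 at an unadjusted p under 0.05), camera 11 lists and fry 0, and 60 of 100 splits gave as many lists, so chance was not excluded. Their medians were -1.63 for erythroid genes, -1.48 for platelets, -0.97 for neutrophil granules, -0.94 for MHC class II, -0.63 for fibroblast matrix, -0.60 for the cell cycle, -0.57 for macrophages, -0.56 for matrix proteases, -0.52 for immediate early genes, 0.28 for oxidative phosphorylation and 0.81 for muscle regeneration. With an estimated correlation their adjusted p ran from 0.654 to 0.846. Calls were lost without young day 3 replicate 1 (neutrophil granules, macrophages, muscle regeneration and oxidative phosphorylation, 0.0982 to 0.881), replicate 2 (fibroblast matrix, 0.275) or replicate 3 (neutrophil granules and muscle regeneration, 0.103 to 0.364), and without young day 5 replicate 1 (muscle regeneration, 0.0767) or replicate 3 (muscle regeneration and oxidative phosphorylation, 0.0996 to 0.157). For the 11 lists the adjusted p over all alternatives ran from 1.25e-17 to 0.881. The fibroblast median of -0.63 turned to 0.20 with the Actb ratio as a covariate and to 0.16 without young day 3 replicates 2 and 3.

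Erdr1 (by the brighter of its 2 tested probe sets, which can cross-hybridise), Mid1 and Wdfy1 set old day 3 and day 5 apart from the other 4 groups, with old day 1 on the side of the young mice. Array scaling is argued against, since the differences on day 3 that came nearest to 0 over 4 other scalings were -4.03 for Erdr1 (interval -4.68 to -3.39), -2.15 for Mid1 (-2.73 to -1.57) and 0.88 for Wdfy1 (0.53 to 1.22), whose brightest probe set was uncalled on day 3 in the report (adjusted p = 0.0775, over the alternatives 2.03e-05 to 0.728). Array brightness or RNA quality is argued against as well: the differences nearest to 0 with either covariate were -4.51 for Erdr1 (-5.32 to -3.70), 1.12 for Wdfy1 (0.65 to 1.60, uncalled at 0.131 and 0.399) and -2.56 for Mid1 (-3.42 to -1.70), although the Actb ratio ended the Mid1 call (adjusted p = 0.0852, from 1.75e-06 to 0.0852 over its alternatives) because the SE grew from 0.30 around -2.67 to 0.41 around -2.56. On pooled days, 8 genes were called apart in old days 3 and 5 from young days 3 and 5. They were also called apart, the same way, from old day 1, and uncalled between ages on day 1. For Crabp2 and Slc27a3 young day 5 (7.95 and 6.52) lay above old day 3 (7.68 and 6.18), so they do not separate the groups fully. Of the 8, Erdr1, Mid1 and G530011O06Rik neighbour each other on chromosome X. Erdr1, Mid1 and Wdfy1 prompted the test and were left out. The other 5 (Crabp2, G530011O06Rik, Nnt, Sfrp1 and Slc27a3) gave 0 pairs at most 3 tested genes apart. Of 10000 random sets 52 gave any. A count of 0 decides nothing at that rate. Nnt, a gene of the strain check, lay at 9.08 to 9.53 on the 6 arrays of old day 3 and day 5 and at 7.81 to 8.87 on the other 12. On its brightest probe set limma did not call Nnt between ages on day 3 or day 5 (adjusted p = 0.167 and 0.527). A strain difference between old mice of day 1 and of later days cannot be told apart from a response to age and healing. That response stays open as untested.

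The fibroblast and granulation tissue matrix score was higher in old mice on day 3, by 0.79 ± 0.28 (SE, interval 0.19 to 1.40). Array brightness as the whole cause is argued against by a difference of 0.66 (0.06 to 1.26) with the spike-in mean as a covariate. The share of skeletal muscle as the whole cause is argued against by 0.67 (0.08 to 1.26) with the muscle score as a covariate. With the Actb ratio the difference was 0.21 (-0.41 to 0.84, SE 0.28), so RNA quality and age cannot be told apart here, because the ratio was higher in young day 3 replicates 2 and 3 than in any old day 3 array. The young day 3 arrays thus leave the difference open to RNA quality, and age stays open as untested.

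The osteoblast and bone matrix score was lower in old mice on day 1, by -1.04 ± 0.29 (SE, interval -1.67 to -0.41). With the Actb ratio as a covariate the difference was -0.96 (-1.69 to -0.24), and with the spike-in mean -1.02 (-1.74 to -0.30). Both measures were higher on each old than on each young day 1 array. The Actb ratio was 2.27 to 2.67 in old and 2.04 to 2.13 in young mice. The adjustment therefore rests on the spread within groups, and neither RNA quality nor array brightness can be told apart from age on day 1. Markers of all other cell types should be raised alike only if bone was diluted by all of them together. Over 10 lists of other cell types the differences ran from -0.47 for B cells to 0.11 for mature neutrophils. That is a gap of 0.58 with an SE of 0.31, and 5 lay above and 5 below 0. Dilution by 1 tissue would raise that tissue's markers alone, which this test cannot see, so dilution and age cannot be told apart. Of lists outside those 10, epidermis, with 4 of its 16 genes measured, differed by 0.62 (0.15 to 1.10) and plasma cells by 0.25 (-0.68 to 1.17), 1.09 ± 0.41 and 0.72 ± 0.19 above B cells, but these gaps were picked as the widest and rest on 4 and 8 genes, so they decide nothing and skin in the old samples stays open too. No unfractured bone was analysed here, so the difference could also precede the fracture, and age stays open as untested.

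Other splits of the same arrays into groups of the same sizes were tested for each count. For comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. On day 1, 1 split gave as many probe sets as the real 64, and the highest other gave 6. On day 3, 2 splits did, with 571 against the real 16. A split that calls several times the real count points to a structure of the samples, here within the day 3 arrays. On day 5, 1 split did (3 against 0). For young mice 1 split did from day 1 to day 3 (3690 against 10) and 1 from day 3 to day 5 (1773 against 553), and for old mice 1 and 1 (8266 against 2, and 164 against 0). For lists, 4 splits gave as many as the real 11 on day 1 (highest other 16), 6 as many as 13 on day 3 (17) and 5 as many as 12 on day 5 (17). In young mice 6 did from day 1 to day 3 (11 against 14) and 5 from day 3 to day 5 (14 against 18), and in old mice 1 did in each interval (15 against 14, and 20 against 19).

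With 100 splits, as many probe sets as the real 8 of the mean over days came from 4 splits, the real split included. That share is under 0.05 but close to it, for 1 of several counts tested, so chance is not firmly excluded. The highest other count, 39, again points to a structure of the samples. For the difference in the change from day 1 to day 3, 1 split of 100 gave as many as 164 (highest other 11). For the F test 1 of 100 gave as many as 18 (highest other 10). In both cases it was the real split. That speaks against a chance division of these arrays, but not of animals if the arrays of a group are technical. For the change from day 3 to day 5 all 100 gave at least the real 0 (highest other 9). Chance was not excluded for the lists of the mean over days (13 of 100, 16 against 19), of the difference from day 1 to day 3 (72 of 100, 10 against 18) and of that from day 3 to day 5 (60 of 100, 11 against 21).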

How the results depend on the processing

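Of the alternatives in this part, the covariates, the fit without young day 3 replicates 2 and 3 and the tests over days 3 and 5 only were chosen only after the result was seen. Each of the 3 covariates differs between the groups, and the lone young day 3 array of that fit is assumed to vary like the other groups.

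A named gene counts here once in each comparison it is named for. None of the 148 called results, from 102 genes, reversed: of 3290 alternative values 2794 kept the call and 496 lost it, and 64 results kept it under every alternative run. Under the alternatives fixed beforehand alone, 2427 of 2765 values and 77 results did. Of 19 uncalled results, from 17 genes, 30 of 414 values gained a call. The spike-in mean as a covariate kept 89 of the 148, the Actb ratio 91 and array weights 139, and without young day 3 replicates 2 and 3 limma kept 37 of 77. Of the 148, 8 rest on a probe set that can cross-hybridise (Erdr1, Trem2 and Aif1), and of 62 whose gene had more than 1 tested probe set, all of them were called in 38 and not all in 24, with 0 called in opposite directions. Of 64 called list results 2 kept their call with an estimated correlation and 23 with fry. Counts are of probe sets called by limma, and the cause of a moved count was not tested unless stated. The medians of 3 list results changed sign. Those of immediate early (0.06) and hypoxia (0.14) genes of old mice from day 1 to day 3 did so with median-centred arrays. The median of all probe sets was then 0.47, so both stayed below other genes and neither direction reversed. The fibroblast difference in the change from day 3 to day 5 did reverse, with the Actb ratio (0.20) and without young day 3 replicates 2 and 3 (0.16). Low signals limit what can be seen, since array median signals of 35.99 to 72.38 lie close to the pseudocount of 16.

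Old minus young on day 1, 64 in the report, gave 6 with the values as deposited, 112 with a pseudocount of 1, 23 with the filter at the 75th percentile, 18 with array weights, 0 from the 6 arrays alone (fewer samples), 0 with the spike-in mean (3373 at an unadjusted p under 0.05 in limma without it), 4 with the Actb ratio and 152 with the muscle score. Without 1 array it gave 10 to 307. On day 3, 16 in the report, the count was 143 with arrays centred on their medians, 8 with a pseudocount of 1, 9 with the stricter filter, 9 without probe sets that can cross-hybridise, 8033 with array weights, 3 from the 6 arrays alone, 2 with the Actb ratio, 29 with the muscle score and 3 without young day 3 replicates 2 and 3. Without 1 array it was 5 to 1605. On day 5, 3 in the report, it was 7 as deposited, 6 centred, 7 with a pseudocount of 64, 1 without cross-hybridising probe sets (fewer tested), 78 with array weights, 6 from the 6 arrays alone and 6 with the muscle score. The mean over days, 8 in the report, gave 5 with the stricter filter, 101 with array weights, 5 with the 2-fold threshold (a stricter rule by construction), 15 with the muscle score, 17 without young day 3 replicates 2 and 3, 15 over days 3 and 5 only, and 3 to 22 without 1 array.

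Young day 3 minus day 1, 3690 in the report, gave 9944 with array weights, 1882 with the 2-fold threshold, 336 from the 6 arrays alone, 521 without young day 3 replicates 2 and 3 and 1525 to 7044 without 1 array. Young day 5 minus day 3, 1773, gave 3005 as deposited, 4761 centred, 12636 with array weights, 1098 with the 2-fold threshold, 15 from the 6 arrays alone, 30 with the spike-in mean, 16 with the Actb ratio, 129 without young day 3 replicates 2 and 3 and 287 to 5523 without 1 array. Old day 3 minus day 1, 8266, gave 12783 centred, 4967 with the stricter filter (fewer tested), 4565 with the 2-fold threshold, 3386 with the spike-in mean, 4790 with the Actb ratio and 5177 to 8306 without 1 array. Old day 5 minus day 3, 164, gave 273 as deposited, 95 and 310 with pseudocounts of 1 and 64, 2000 with array weights, 1246 from the 6 arrays alone, 84 with the spike-in mean, 359 with the Actb ratio, 392 with the muscle score and 49 to 148 without 1 array.

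The difference in the change from day 1 to day 3, 164, gave 280 as deposited, 2067 centred, 108 with a pseudocount of 1, 82 with no filter, 95 with the stricter filter, 2535 with array weights, 4 from the 12 arrays alone, 1 with the spike-in mean, 0 with the Actb ratio (4360 at an unadjusted p under 0.05 in limma without it), 8 without young day 3 replicates 2 and 3 and 6 to 1737 without 1 array. That from day 3 to day 5, 0 (1791 at an unadjusted p under 0.05 in limma), gave 4806 with array weights, 1 from the 12 arrays alone and 0 to 8 without 1 array. The F test, 18, gave 3 as deposited, 264 centred, 7 with a pseudocount of 64, 10 with no filter, 8 with the stricter filter, 4297 with array weights, 2 with the spike-in mean, 2 with the Actb ratio, 36 with the muscle score, 7 without young day 3 replicates 2 and 3 and 2 to 731 without 1 array.

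The estimated correlation called 0 lists in each comparison but old day 5 minus day 3, where it called 2. Of all 35 lists fry called 0 in the 4 comparisons of ages. In young mice it called 5 for the earlier interval and 12 for the later, of which 5 and 8 were among the 11 and 14 that camera called. In old mice it called 9 and 8, of which 8 and 8 were among 15 and 20, and for the differences in change 1 and 0, of which 1 and 0 were among 10 and 11. The counts that follow are also over all 35 lists, so a list may be called under an alternative alone. On day 1 camera called 11, against 7 with the spike-in mean and 7 to 14 without 1 array. On day 3 it called 13, against 8 with the Actb ratio and 8 to 14 without 1 array. It called 10 for the earlier difference in change, against 6 to 14 without 1 array, and 11 for the later one, against 17 without young day 3 replicates 2 and 3.

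Replicate numbers did not pair the samples: of 45 pairs of same-numbered arrays, 3 for each of 15 pairs of groups, 5 had a correlation of their deviations over 0.1 (range -0.50 to 0.36, median -0.02). With the replicate number as a block the count was 8 for old minus young on day 3, 5 for the mean over days, 105 for the difference in the change from day 1 to day 3 and 10 for the F test, and it moved by less than 1.5 times for the other 7 counts.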

Other observations

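Of the tests in this part, the mislabelling check of young day 3 was chosen only after the result was seen.

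Single members of the endothelial, adipocyte, senescence and unfolded protein response lists were called between day 1 and day 3, with members of each list on both sides of 0. Aplnr, the apelin receptor of sprouting endothelium, rose by 2.75 ± 0.38 (limma, adjusted p = 0.000381) in young and 2.91 ± 0.38 (5.26e-05) in old mice, while Flt1, a VEGF receptor, changed by -1.02 ± 0.23 (0.00861) and -1.09 ± 0.23 (0.00223). The adipogenic regulator Pparg rose by 1.93 ± 0.38 (0.00424) and 2.10 ± 0.38 (0.000824), and Pnpla2, the lipase that starts fat breakdown, changed by -2.23 ± 0.44 (0.00379) and -2.43 ± 0.44 (0.000708). Serpinh1, the collagen chaperone, rose by 1.33 ± 0.28 (0.00558) and 2.60 ± 0.28 (9.71e-06), and the cell cycle inhibitor gene Cdkn1a changed by -1.87 ± 0.23 (0.000198) and -1.58 ± 0.23 (0.000165). Atf4, a stress response factor, changed by -1.12 ± 0.13 (0.000112) in young mice. For each gene the 3 arrays of day 3 lay past all 3 of day 1. Flt1 lost its call in young mice without young day 3 replicate 3 (adjusted p = 0.0503, over its alternatives 0.000109 to 0.341).

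Of 22 hypoxia and glycolysis genes, 1 rose and 4 fell in young mice from day 1 to day 3, or 1 and 10 adjusted over the list alone (median -0.53, camera, adjusted p = 0.00192, and adjusted p = 0.765 with an estimated correlation). In old mice 3 rose and 9 fell, or 4 and 9 adjusted over the list alone (camera, adjusted p = 0.0203, and adjusted p = 0.647 with an estimated correlation), with a median of -0.52. With arrays centred on their medians it was 0.14, below the 0.47 of all probe sets, but camera did not call the list (adjusted p = 0.0797). It also lost its call in old mice without old day 1 replicate 3 (0.122) or old day 3 replicate 3 (0.0502), over all alternatives of the 10 lists 1.33e-14 to 0.995. Slc2a1, the basal glucose transporter, changed by -1.68 ± 0.22 (0.000284) in young and -1.37 ± 0.22 (0.000352) in old mice, and the collagen hydroxylase gene P4ha2 rose by 1.48 ± 0.32 (0.00285) in old mice. Of 24 interferon response genes 9 rose and 1 fell in young mice, or 12 and 2 adjusted over the list alone (median 0.82, camera, adjusted p = 0.00103, and adjusted p = 0.869 with an estimated correlation). The antiviral genes Ifit3 and Mx1 rose by 2.06 ± 0.47 (0.00898) and 1.90 ± 0.45 (0.0115), and Mx1 lost its call without young day 3 replicate 3 (0.0686, over its alternatives 0.000145 to 0.124). For each of these 4 genes the 3 arrays of day 3 lay past all 3 of day 1.

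The labels give 2 different strains. H2-Ea, which mice of the H2-b haplotype such as C57BL/6 do not make, reached at most 53.8 on any array and exceeded the array median on 0 of 18, while its partner gene H2-Eb1 gave 280 to 1580. Signals this low in all 6 groups are what the C57BL/6 line of the design text would give. No group showed the signal of a strain that makes H2-Ea. Nnt, part of which is deleted in C57BL/6J, lay at 9.08 to 9.53 on the 6 arrays of old day 3 and day 5 and at 7.81 to 8.87 on the other 12.

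A test of whether young day 3 arrays held day 1 samples was run first and argued against it, and its place among the 3 explanations weighed for the fibroblast list was given to the RNA quality test after both results were known. The macrophage score was -0.64 to -0.73 in young day 1, and -0.04, 0.60 and 0.98 in young day 3 replicates 1, 2 and 3.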
